A study of Mus musculus with 2 samples.

How the data were processed

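MicroRNA-seq counts short RNAs, here a size class below 30 nucleotides per the labels, taken from total RNA. The tissue was heart dissected from healthy mouse embryos at 13.5 days, strain B6NCrl, with both sexes mixed. The labels name 2 libraries as biological replicates from separate biosamples of 1 donor or strain record. The design therefore has 1 group with 2 libraries (n = 2) and no comparison between groups.

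The deposited tables hold whole-number read counts per miRNA gene, which the authors derived from an alignment to mm10 with GENCODE annotation M4, per the notes deposited with the tables. The aligner, the counting tool, adapter trimming and their versions are not given in the sources used here. Each deposited table has 1973 gene rows and 4 rows of read classes. The columns hold counts on both strands, on the strand of the gene (sense) and on the opposite strand. The both-strand count equalled the sense plus the opposite count at all 1973 genes in both libraries. Reads that mapped to several places form a read class of their own and are taken here to be in no gene row, which no source states. If so, a miRNA made from several identical loci is undercounted in these tables. The read classes held 21.2% unmapped and 26.9% multi-mapping reads in replicate 1. They held 17.2% and 28.0% in replicate 2. Reads outside any miRNA gene made up 3.60% and 2.92%. These classes stayed out of library sizes and tests.

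Sense counts were used throughout. They totalled 5569959 in replicate 1 and 6039005 in replicate 2, and counts per 1000000 (CPM) were computed on these totals. A count of 0 allowed up to 3 counts, which is 0.539 CPM in replicate 1 and 0.497 CPM in replicate 2. Shares of 1 library carry exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

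Gene symbols, coordinates and host genes came from GENCODE M21 on the same build, matched by gene identifier. Of the 1973 identifiers, 1894 matched, and no count above 2 lay at any of the 79 others. Coordinates are 1-based on mm10. A locus was said to lie in an exon or intron where a transcript on the same strand spans it.

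Before the data were examined, 18 gene lists were fixed, of which 11 hold miRNAs known from a cell type and 7 hold families or genomic clusters. They name 182 symbols, of which 163 had a row in the tables. Genes named in the text were the 20 most abundant by mean CPM, every measured member of the cardiomyocyte list, the 3 most abundant members of each other list, all members of the miR-17 clusters, and the 5 largest changes in each direction among genes that differed between the libraries. Any other gene named was chosen after its values were seen.

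The libraries were compared across genes at a mean of 10 CPM or more. Pearson and Spearman coefficients used log2(CPM + 1) and carry no p-value, since genes are not replicates. A common biological coefficient of variation was estimated with edgeR 4.0.16 in R 4.3.3 from an intercept-only model with TMM factors. DESeq2 1.42.0 size factors were an alternative. Single genes were tested with a two-sided exact conditional binomial test on their counts in the 2 libraries, with total counts as offset and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and a ratio of at least 1.5 with a pseudocount of 1 CPM. This test compares those libraries, not conditions. For lists with at least 3 members at 10 CPM, the median log2 ratio was placed among 10000 random lists of equal size matched on mean CPM in 10 bins. With 2 libraries an exact sign-flip permutation test cannot go below 0.5, so levels of lists were compared through their direction in each library and the SD of the log2 ratio.

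The binomial step was tested on simulated counts of replicate 1 against replicate 2 over 284 genes. It recovered 199 of 200 genes changed by 2-fold, with 0 false calls. Simulated counts without a change gave 0 genes at an adjusted p under 0.05 at any ratio, against 177 of 288 between the real libraries. The simulated spread was therefore smaller, and the absence of false calls does not cover the real spread between libraries. On counts simulated with a coefficient of variation of 0.1, the dispersion step gave 0.104 over 291 genes. Alternatives were TMM or DESeq2 scaling, other CPM minimums, another pseudocount, a ratio of 2, both strands, loci without copies, shares without the most abundant gene, and each library left out in turn. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.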

Results

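MicroRNA-seq counted short RNAs in hearts of mouse embryos at 13.5 days, in 2 libraries from separate biosamples. Replicate 1 held 12136246 reads, of which 5569959 (45.9%) were counted on the sense strand of a miRNA gene. Replicate 2 held 12282789 reads, of which 6039005 (49.2%) were so counted. The labels give the tissue and the age and no second condition. The questions open to these data are which miRNAs the embryonic heart held, how the miRNAs of heart muscle compared with those of other cell types, and how far the libraries differed.

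The most abundant miRNA gene was Mir335 at 110067 ± 2450 CPM (SD, n = 2), or 11.01% ± 0.245 of all sense counts. Mir335 (ENSMUSG00000065501.1, chromosome 6, 30741299 to 30741396) lies in an intron of Mest, an imprinted gene expressed in mesoderm. Next came Mir143 at 88435 ± 5892 CPM, known from smooth muscle, and Mir322 at 84203 ± 9297 CPM on the X chromosome. Mir126a, whose host Egfl7 is an endothelial gene, reached 70450 ± 6259 CPM. Mir99a reached 65577 ± 946 CPM and Mir208b, in an intron of the cardiac myosin gene Myh7, 42964 ± 1728 CPM. Mirlet7g at 41765 ± 1597 CPM, Mirlet7i at 39792 ± 4521 CPM, Mir26b at 27782 ± 2723 CPM and Mir351 at 27754 ± 1047 CPM completed the first 10. This ranking uses sense counts only. Counts opposite to the row of Gm25301, on the strand of Mir378a, would place Mir378a at rank 9 with 35112 ± 2953 CPM. The order of Mir26b and Mir351 differed between the libraries, and Mirlet7i lay above Mirlet7g and Mir208b in replicate 1 only. The genes ranked 11 to 20 were Mir30e, Mir23a, Mir17, Mir130a, Mir99b, Mir21a, Mir23b, Mir652, Mir30a and Mirlet7d, from 24096 ± 2154 CPM for Mir30e down to 10621 ± 816 CPM for Mirlet7d.

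The first 10 genes took 59.9% ± 0.547 of the counts. In replicate 1 they took 59.49% (exact 95% interval 59.45 to 59.53) and in replicate 2 60.27% (60.23 to 60.30). The first 20 took 77.2% ± 0.660 and the first 50 took 91.1% ± 0.271. In both libraries 281 genes reached 10 CPM, and 175 reached 100 CPM. No count fell on 1281 of the 1973 genes in either library.

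Among the miRNAs of cardiomyocytes, Mir208b was the highest, followed by Mir208a at 7263 ± 121 CPM and Mir499 at 1825 ± 281 CPM. Each lies in an intron of a myosin heavy chain gene: Mir208b in Myh7 (chromosome 14, 54975700 to 54975776), Mir208a in Myh6 (chromosome 14, 54949060 to 54949142) and Mir499 in Myh7b (chromosome 2, 155622880 to 155622958). Myh7 is the main myosin of the fetal mouse ventricle and Myh6 of the adult one. Mir208b had 5.91 times the counts of Mir208a, a log2 ratio of 2.56 ± 0.0821 (SD, n = 2). The ratio was 5.68 in replicate 1 (exact 95% interval 5.62 to 5.74) and 6.16 in replicate 2 (6.09 to 6.22). The counts of the muscle miRNAs miR-1 and miR-133a stayed low at their own rows. Mir1a-1 held 25 and 22 counts (4.07 ± 0.598 CPM) and Mir133a-1 held 11 and 23 counts (2.89 ± 1.30 CPM). Mir133a-2 held 0 counts in both libraries, which allows up to 0.539 CPM in replicate 1 and 0.497 CPM in replicate 2. Mir1a-2 has no row of its own; 98 counts in each library lay opposite to the row of Mir1b, on the strand of Mir1a-2, which would be 16.1 ± 0.944 CPM (looked up after the data were seen). Mature miR-1 and miR-133a each come from more than 1 locus, and if reads that map to several places are in no gene row, as taken here from their separate read class, these values are lower bounds on the mature miRNAs.

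The cardiomyocyte list as a whole took 5.21% ± 0.189 of the counts. It lay below the endothelial list, which took 11.1% ± 0.677 with Mir126a, Mir23a (20213 ± 457 CPM) and Mir130a (19260 ± 53.2 CPM) in front. The endothelial share was 2.12 times the cardiomyocyte share, a log2 ratio of cardiomyocyte over endothelial of -1.09 ± 0.141. It also lay below the smooth muscle and epicardium list, which took 8.93% ± 0.594, nearly all from Mir143. Mir145a of the same primary transcript held 899 ± 44.7 CPM, and Mir145b held 1 count in replicate 1 and 0 in replicate 2. That list was 1.71 times the cardiomyocyte share (log2 ratio of cardiomyocyte over it -0.78 ± 0.0436). With few reads at the rows of Mir1a and Mir133a, these ratios describe the deposited rows rather than the cell types.

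The cardiomyocyte share was above the other 8 of 10 cell type lists in both libraries. It was 2.54 times that of mesenchyme and fibroblast miRNAs, which took 2.05% ± 0.0743. Of these, Mir21a held 17004 ± 1115 CPM (1.70% of all sense counts), Mir214 2757 ± 333 CPM and Mir199b 399 ± 49.5 CPM. Pluripotency-associated miRNAs took 0.260% ± 0.0201, and Mir302a (1061 ± 55.4 CPM), Mir302d (720 ± 114 CPM) and Mir302b (625 ± 33.1 CPM) led them. Epithelial miRNAs took 0.216% ± 0.0378, with Mir429 at 884 ± 156 CPM, Mir200c at 432 ± 93.2 CPM and Mir203 at 362 ± 54.9 CPM. Erythroid miRNAs took 0.111% ± 0.0213, with Mir451a at 775 ± 117 CPM, Mir144 at 253 ± 67.8 CPM and Mir486 at 81.8 ± 28.1 CPM. Endoderm and liver miRNAs took 0.108% ± 0.0373, with 0.0812% in replicate 1 and 0.134% in replicate 2. The leukocyte list took 0.0589% ± 0.0103 with Mir223 at 375 ± 92.6 CPM, Mir155 at 155 ± 11.99 CPM and Mir146 at 49.98 ± 21.7 CPM. The skeletal muscle list, Mir206 (97.6 ± 25.5 CPM) and Mir133b (3.29 ± 0.675 CPM), took 0.0101% ± 0.00248. The neural list took 0.00876% ± 0.00254, and 4 of its 8 rows held no count. Its highest members were Mir137 (67.9 ± 21.5 CPM), Mir219a-1 (13.2 ± 2.70 CPM) and Mir219a-2 (4.58 ± 0.383 CPM). The cardiomyocyte share was 524 times the skeletal muscle share and 607 times the neural share. Every neural row except Mir137 is a copy of a miRNA with several loci, and Mir133b shares a 20-nucleotide run with another locus. In the mesenchyme and fibroblast list, Mir199a-2, Mir199b and Mir29b-1 share a 22-nucleotide run with another locus. If multi-mapping reads are in no gene row, such rows are undercounted. The ratios to the skeletal muscle, neural, and mesenchyme and fibroblast lists therefore describe the deposited rows rather than the cell types. In each of the 17 comparisons with other lists the log2 ratio was larger than its SD between the libraries. The leukocyte share became 0.183% when counts on the opposite strand were given to Mir142, a choice made after the data were seen. It was also 0.183% with both strands counted, an alternative set before.

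**Figure D1:**
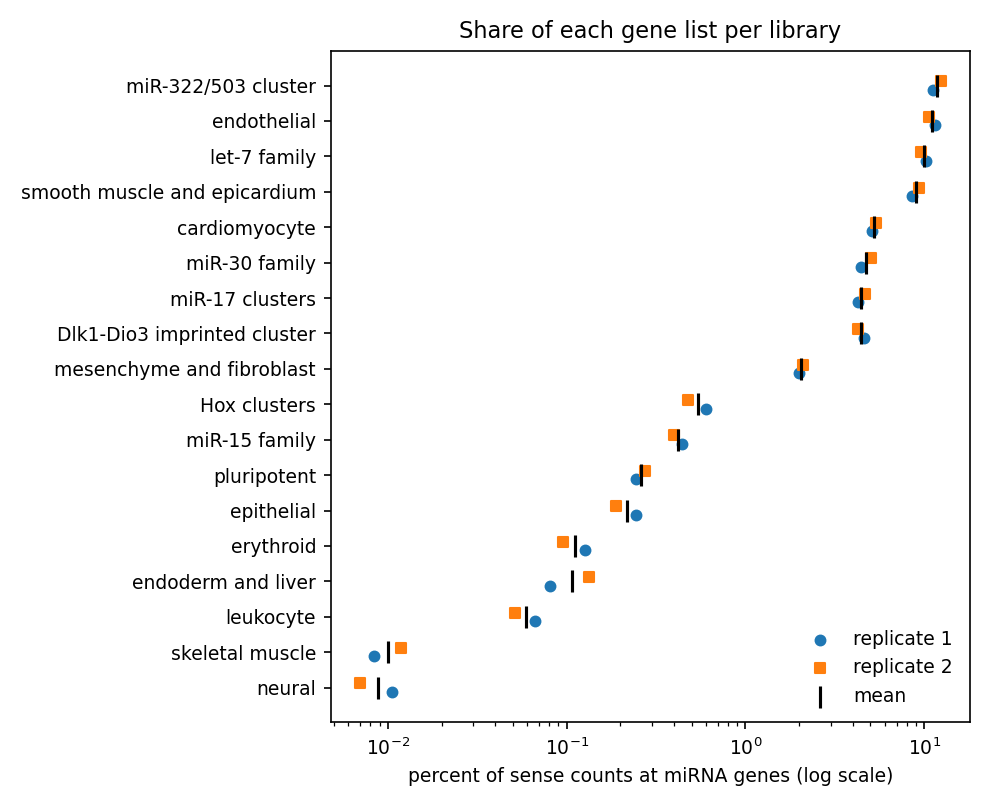
Percent of sense counts at miRNA genes (log axis) for each of the 18 gene lists; circles are replicate 1, squares replicate 2 and vertical bars their mean. The cardiomyocyte list, at 5.21%, lies below 4 lists, and the lists span from 0.00876% (neural) to 11.8% (the cluster of Mir322).

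Among families and clusters, the cluster of Mir322 on the X chromosome, known from cell cycle exit and muscle differentiation, took the highest share of counts at 11.8% ± 0.825 (log2 ratio of cardiomyocyte over it -1.17 ± 0.0490). Mir322 (chromosome X, 53054255 to 53054349) exceeded Mir351 by 3.03-fold (log2 1.60 ± 0.214) and Mir542, at 2517 ± 155 CPM, by 33.4-fold (log2 5.06 ± 0.0709). The let-7 family, which rises with differentiation in many tissues, took 9.92% ± 0.433 (log2 ratio of cardiomyocyte over it -0.93 ± 0.115). Mirlet7a-1, Mirlet7a-2, Mirlet7c-1, Mirlet7c-2 and Mirlet7f-2 share a 22-nucleotide run with another locus. If multi-mapping reads are in no gene row, the let-7 share is an undercount, and its rank below the Mir322 cluster describes the deposited rows. It was 9.88% with opposite-strand counts, those of Mirlet7e included, reassigned after the data were seen. The miR-30 family took 4.73% ± 0.398 (0.14 ± 0.0691), with Mir30d at 9313 ± 191 CPM behind Mir30e and Mir30a (13655 ± 1612 CPM). The miR-15 family list took 0.420% ± 0.0337 (0.274% without loci that have a copy). Its highest rows were Mir15a at 1737 ± 170 CPM, Mir16-1 at 1284 ± 82.2 CPM and Mir15b at 689 ± 48.4 CPM. That list does not hold Mir322, which was counted only with its cluster, so its share depends on that choice of members. The miRNAs of the Hox clusters took 0.540% ± 0.0914, with Mir10a (4407 ± 631 CPM), Mir10b (732 ± 230 CPM) and Mir196b (168 ± 21.2 CPM) in front. The imprinted Dlk1-Dio3 cluster on chromosome 12 took 4.44% ± 0.237, and 40 of its 44 measured members reached 10 CPM in both libraries. Mir487b held 7566 ± 11.9 CPM, Mir411 7120 ± 707 CPM and Mir127 4807 ± 125 CPM. The cardiomyocyte share was 1.17 times that of the Dlk1-Dio3 cluster (log2 0.23 ± 0.129). That difference ended, at a log2 ratio of 0.0025, when opposite-strand counts were given to the miRNA on that strand.

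The miR-17 clusters, known from proliferation of the embryonic heart, took 4.45% ± 0.287, or a cardiomyocyte share 1.17 times as high (log2 0.23 ± 0.0409). Mir17 led the cluster on chromosome 14 at 19922 ± 1221 CPM, 2.44 times Mir20a (8186 ± 930 CPM; log2 1.29 ± 0.0758). Mir18 held 2763 ± 176 CPM and Mir92-1 held 1977 ± 224 CPM. Mir19a held 26.9 ± 2.27 CPM and Mir19b-1 held 5.81 ± 1.18 CPM. The cluster in Mcm7 on chromosome 5 held Mir93 at 7108 ± 622 CPM, Mir106b at 4061 ± 201 CPM and Mir25 at 292 ± 23.98 CPM. The third cluster, on the X chromosome, held between 0.752 ± 0.810 CPM (Mir19b-2) and 56.3 ± 6.99 CPM (Mir106a). Its other members were Mir92-2 at 41.1 ± 1.25 CPM, Mir20b at 36.8 ± 8.32 CPM, Mir363 at 34.0 ± 8.77 CPM and Mir18b at 6.46 ± 0.0037 CPM. Mir106a was 355-fold below Mir17 (log2 ratio of Mir17 over Mir106a 8.47 ± 0.268). Mir92-1, Mir92-2, Mir19b-1 and Mir19b-2 share a 22-nucleotide run with another locus. If multi-mapping reads are in no gene row, their rows are lower bounds on the mature miRNAs.

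The rows of miRNAs with several loci held few counts: 121 loci whose symbols carry a copy number took 0.909% ± 0.0437 of the counts. In 18 of 20 genomic clusters, members that share a 22-nucleotide run with another miRNA locus had a lower median level than their neighbours without one. The median difference was -4.09 on the log2 scale (exact sign test over clusters, two-sided, p = 0.000402), and -3.31 with a run of 20 nucleotides. The test takes clusters as independent, although copies of 1 miRNA, such as Mir194-1 and Mir194-2, fall in different clusters. The cluster of Gm22072 counts as lower on medians of 0 against 0.262 CPM. Mir99a at 65577 CPM lay beside Mirlet7c-1 at 103 ± 15.1 CPM, and Mirlet7d at 10621 CPM beside Mirlet7a-1 at 87.6 ± 16.2 CPM. Clusters were formed after the data were seen, from genes whose starts lie at most 10000 nucleotides apart on 1 strand.

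**Figure D2:**
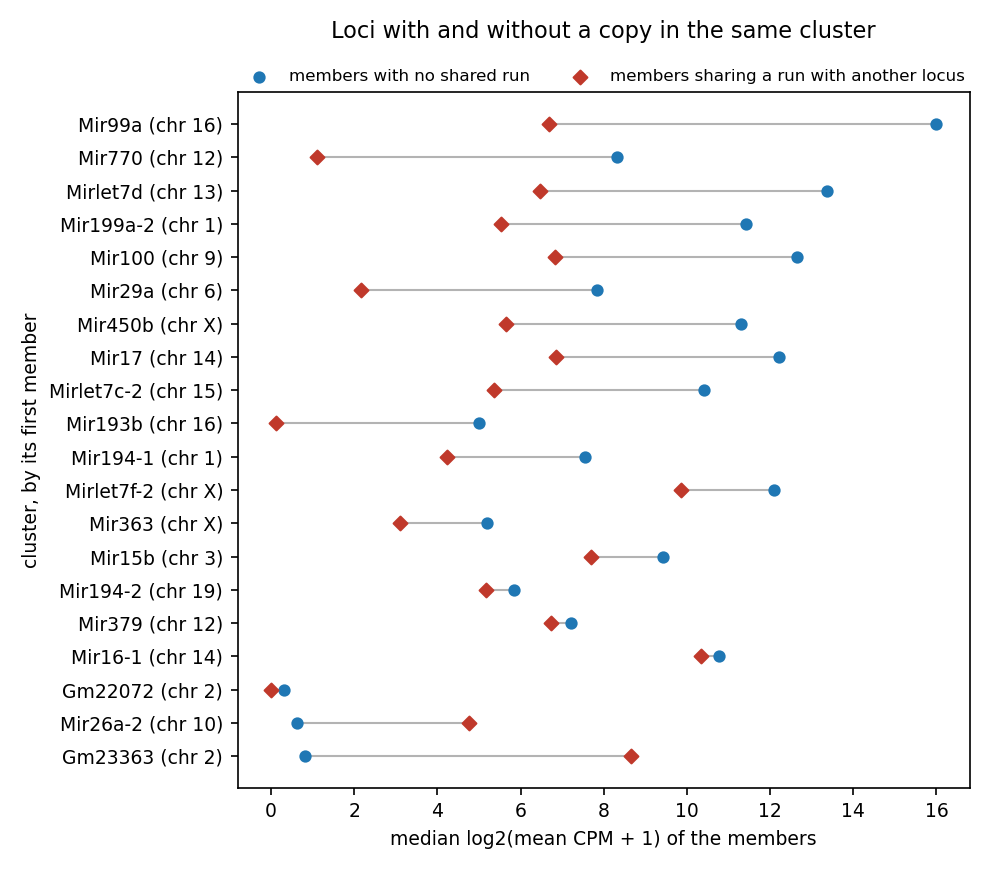
Median log2(mean CPM + 1) of members that share a 22-nucleotide run with another locus (diamonds) and of members that do not (circles), for 20 genomic clusters named by their first member and chromosome. Diamonds lie to the left in 18 clusters; the exceptions are those of Mir26a-2 and Gm23363, whose neighbours without a shared run lie near 0.

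The libraries had a Pearson r of 0.996 and a Spearman rho of 0.994 across 288 genes, which are not independent replicates. The median absolute log2 ratio between them was 0.16. The common biological coefficient of variation was 0.125. Set against read sampling alone, with PCR copies counted as independent reads, the counts had a chi-square of 35589 on 287 degrees of freedom. An adjusted p under 0.05 in the exact binomial test was reached at 177 genes (61.5%), and 17 of these also passed the ratio of 1.5.

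The largest difference was at Mir122, the main miRNA of hepatocytes, with 201 CPM in replicate 1 and 591 CPM in replicate 2 (log2 replicate 1 over replicate 2 -1.55, exact binomial test, adjusted p = 1.46e-250). Mir375, known from endocrine endoderm, was also higher in replicate 2 (301 against 471 CPM, log2 -0.65), as was Mir758 of the Dlk1-Dio3 cluster (9.16 against 15.7 CPM, log2 -0.72). Higher in replicate 1 were Mir6240 (log2 1.18), Mir146 (0.90), Mir615 in an intron of Hoxc5 (0.79), Mir6236 (0.77), and Mir294 and Mir129-2, which tied at 0.73. In all, 14 genes were higher in replicate 1 and 3 in replicate 2. TMM scaling lowered every replicate 1 over replicate 2 ratio by 0.10 on the log2 scale and called 16 genes, 8 higher in each library. Of these 16, 11 were among the 17. The calls of Mir122, Mir375, Mir758, Mir6240, Mir146, Mir615, Mir6236, Mir294 and Mir129-2 did not depend on that scaling. This test compares the reads of these libraries, and no condition.

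**Figure D3:**
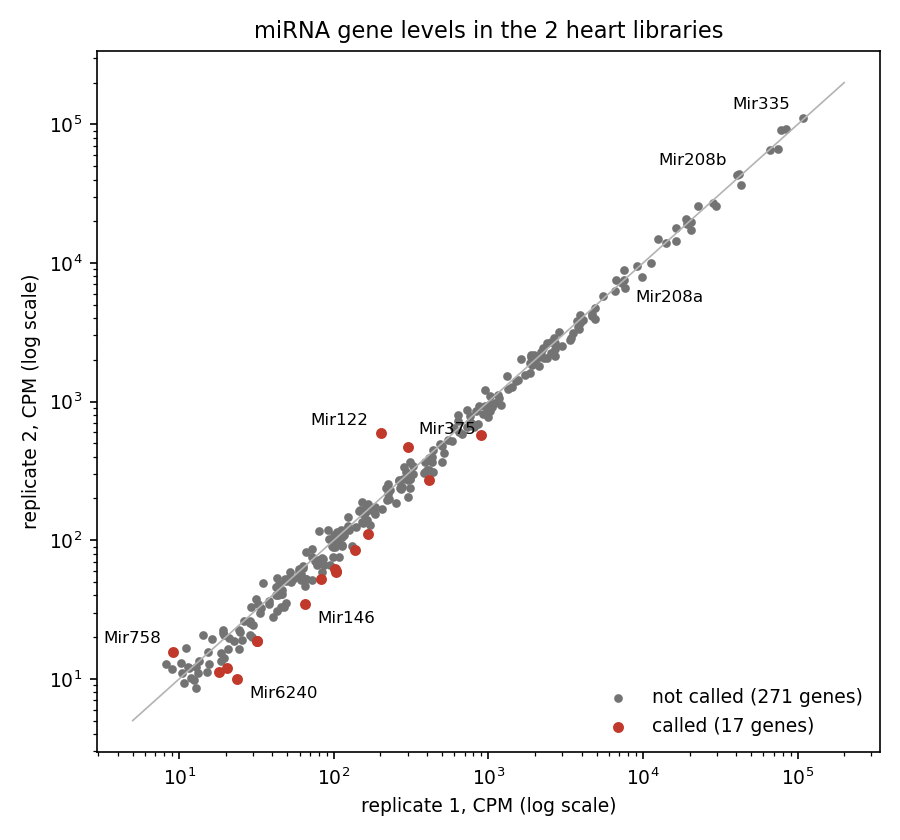
CPM in replicate 2 (vertical) against replicate 1 (horizontal), both on log axes, for the 288 miRNA genes at a mean of 10 CPM or more; red points are the 17 called genes and the line marks equal values. Mir122 lies farthest above the line and Mir6240 farthest below it among the called genes.

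By list, the erythroid miRNAs Mir451a, Mir144 and Mir486 were higher in replicate 1 at 3 of 3 members, with a median log2 ratio of 0.55 at percentile 98.9 of random lists. The median of all 288 genes was itself 0.10 on total counts, so a ratio slightly above 0 is typical of these libraries. Random lists were drawn gene by gene, so percentiles treat neighbours such as Mir144 and Mir451a, or Mir200a, Mir200b and Mir429, as independent. They can therefore overstate how unusual a list with such neighbours is. Leukocyte miRNAs had a median of 0.51 (percentile 98.6), with Mir223 at 441 CPM in replicate 1 and 310 CPM in replicate 2; Mir155 went the other way (log2 -0.16). On total counts 7 of 7 epithelial miRNAs had a ratio above 0, with a median of 0.31 (percentile 97.8), and 5 of them had an adjusted p under 0.05 in the exact binomial test. Under TMM scaling 6 of 7 stayed above 0, with Mir141 at -0.03 (0.08 on total counts). All 4 Hox cluster miRNAs at a mean of 10 CPM or more, of 6 with a row, were higher in replicate 1, with a median of 0.47 (percentile 99.7). Calls at single members of these 4 lists were Mir486, Mir146, Mir205, Mir10b and Mir615, and adjusted over the list alone the counts per list were equal. Mir205 and Mir10b were not called under TMM scaling. Endoderm and liver miRNAs had a median of -0.25 (percentile 0.16), led by Mir122 and Mir375, and Mir215 had the opposite sign at 0.29. The miR-30 family had a median of -0.21 (percentile 0.065), with 0 of 6 members higher in replicate 1 and none called. The other 9 of 15 lists lay within the central 95% of random lists. Their medians ran from -0.11 for the pluripotency list to 0.18 for the let-7 family, with -0.08 for cardiomyocyte, 0.07 for endothelial, 0.04 for mesenchyme and fibroblast, 0.11 for the miR-17 clusters, 0.14 for the miR-15 family, -0.06 for the Mir322 cluster and 0.16 for the Dlk1-Dio3 cluster. Under TMM scaling the endothelial and mesenchyme medians changed sign. The leukocyte list moved inside the central range (percentile 92.8) when members at 1 CPM or more were used, and the epithelial list (percentile 97.3, median 0.31) after a correction for hairpin GC content chosen after the data were seen, because it lay close to the edge of that range.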

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

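The tests of strand, of shared sequence, of GC content and of a lower heart muscle share were chosen after the results were seen; a GC correction set before its result is not used as a test, because it moved no list median by more than 0.0136, although the epithelial list went from percentile 97.8 to 97.3, inside the central range.

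Counts on the strand opposite to the annotated gene were looked at because the comparisons above do not use them, and they lay above what a count of 0 allows. They made up 4.96% of assigned reads in replicate 1 and 5.18% in replicate 2. The row of Gm25301 alone, with no sense count, held 193535 and 236922 of them. Mir378a, a miRNA in an intron of the metabolic coactivator gene Ppargc1b, lies there on the other strand (chromosome 18, 61397835 to 61397900), and these counts would place it at rank 9 with 35112 ± 2953 CPM. Of all opposite-strand counts, 99.96% in both libraries lay in rows where GENCODE M21 has a miRNA gene on that strand, among them Mirlet7e, Mir409, Mir191 and Mir142. Loss of strand in the library is argued against, since 274 rows at 10 CPM or more with no such gene held at most 0.0022% of their counts on the opposite strand. These values go with rows annotated opposite to the transcribed miRNA; no biological explanation was tested, since the design has 1 group.

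Reads that mapped to several places were the other signal outside the gene rows, with 26.9% of all reads in replicate 1 and 28.0% in replicate 2. The low counts at Mir1a-1, Mir133a-1 and Mir133a-2, miRNAs that are abundant in heart muscle in other work, may come from reads kept out of the gene rows, though no source names the counting tool or says how it treats such reads. Mir1a-2, which has no row of its own, had 98 counts in each library on its strand opposite to the row of Mir1b. Members of a cluster are often cut from 1 primary transcript. Those that share a 22-nucleotide run with another locus lay below their neighbours in 18 of 20 clusters (exact sign test, p = 0.000402), by 17.0-fold at the median. The test takes clusters as independent, although some hold copies of the same miRNA. With a run of 20 nucleotides the count was 19 of 23 clusters (exact sign test, p = 0.0026) and the median fold 9.90. Not every low row has that property: Mir19a, with no such run, lay 740-fold below Mir17 of the same cluster. No biological explanation was tested, and the level of mature miR-1 and miR-133a in these hearts stays open.

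Of 15 gene lists, 6 lay outside the central 95% of random lists between the libraries, on percentiles that treat members of 1 genomic cluster as independent. A straight-line trend with the GC content of the hairpins is argued against as the whole cause: the correlation of the log2 ratio with GC was 0.0241 across 288 genes, and at the far end of its 95% interval the trend gives at most 4.50% of the shift of any of these 6 lists from the median gene. A lower share of heart muscle in replicate 1, as the only difference, would raise the miRNAs of every other cell type. The endoderm and liver list lay at percentile 0.16 while the erythroid list lay at 98.9, and such a share alone would not give both directions. These percentiles are the pattern to be explained and were known before the criterion was set, so they are no separate test of it. A lower heart muscle share combined with other differences in tissue was not tested. The cardiomyocyte share was 5.07% in replicate 1 and 5.34% in replicate 2. Different amounts of neighbouring tissue in the dissections, such as liver for Mir122, remain a candidate explanation. Without Mir122 the other 5 endoderm and liver members still lay at percentile 0.745, though Mir192 and Mir215 did not share the direction of Mir122. That median is the value of Mir194-1 (log2 -0.23, exact binomial test, adjusted p = 0.309), and Mir194-2 is a copy of the same miRNA. Among these 5, only Mir375 and, in the other direction, Mir215 had an adjusted p under 0.05 in that test. Blood content, embryo stage within the pool and library preparation were not tested, and the labels name no batch.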

How the results depend on the processing

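Giving opposite-strand counts to the miRNA on that strand, the GC correction and leaving out Mir122 were chosen after the data were seen; the other alternatives were not. No called direction reversed in 432 recomputed values, and 378 kept their call, moved by less than the SD between libraries or, for counts and coefficients, stayed within 1.5 times (for correlations, of 1 minus r). Part of the 378 was fixed in advance. With 2 libraries, leaving 1 out moves a mean share or log2 ratio by less than its SD whatever the data. TMM scaling lowers every ratio about alike, so the percentile of a list could hardly change under it. Genes in both libraries numbered 281 at 10 CPM, 396 at 1 CPM and 175 at 100 CPM. TMM scaling called 16 genes in place of 17, with 11 shared, and 8 and 8 by direction in place of 14 and 3. The miR-15 family share was 0.274% without loci that have a copy. The share of the first 10 genes was 60.4% without loci that have a copy, 57.7% with both strands counted and 57.7% with opposite-strand counts reassigned. With no filter on low counts, Pearson r was 0.993, Spearman rho 0.921, and 45 genes differed between the libraries (31 higher in replicate 1, 14 in replicate 2). A ratio of at least 2 left 2 genes, 1 in each direction, because fewer genes can pass it. The cardiomyocyte share was 4.94% with both strands counted, 4.94% with opposite-strand counts reassigned and 5.85% without Mir335 in the total, as the total itself changes. Of 391 values for single lists and genes, 41 moved by more than their SD and 2 list shifts fell inside the central range (leukocyte with members at 1 CPM or more, epithelial after the GC correction). After reassignment the cardiomyocyte share stayed above 12 of 17 lists, in place of 13. Each library alone also gave 13, which follows from the count, since all 17 ratios had the same direction in both libraries. No paired analysis was possible because the design has 1 group. Depth limits the genes near the floor of 0.539 and 0.497 CPM.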

Other observations

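Imprinted loci outside chromosome 12 also held abundant miRNAs, chosen after their values were seen. Mir335 in Mest, Mir483 in an intron of the fetal growth factor gene Igf2, Mir675 in an exon of H19, and Mir296 and Mir298 together took 11.8% ± 0.175 of the counts (SD, n = 2). Mir483 held 3339 ± 267 CPM, Mir296 2405 ± 407 CPM, Mir298 1963 ± 36.4 CPM and Mir675 170 ± 9.56 CPM. The miR-99 group of Mir99a, Mir99b and Mir100 took 9.08% ± 0.334, of which Mir100 held 6412 ± 236 CPM. The X chromosome, with Mir322 and Mir351, took 14.8% ± 0.775, with 32 of its genes at 10 CPM or more.

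By position, miRNA genes inside a protein-coding gene on the same strand, 120 of them at 10 CPM or more, took 49.0% ± 0.624 of the counts. Intergenic miRNA genes, 99 of them at 10 CPM or more, took 35.9% ± 0.7496. The miR-302 group (Mir302a to Mir302d, with Mir367), known from pluripotent cells, took 0.249% ± 0.0212, and Mir367 of the same cluster held 3 counts in replicate 1 and 0 in replicate 2. The miR-290 group, also known from pluripotent cells, took 0.0112% ± 0.00108. The cluster of Mir183 (341 ± 101 CPM), Mir96 (111 ± 35.7 CPM) and Mir182 (350 ± 53.3 CPM), known from sensory cells, took 0.0802% ± 0.0190. Mir183 and Mir96 were called higher in replicate 1 (log2 0.61 and 0.66) on total counts but not under TMM scaling, and Mir182 had a log2 ratio of 0.31.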
